A study of Mus musculus with 8 samples.

How the data were processed

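Single-cell RNA sequencing was run on cells dissociated from the livers of mice treated with carbon tetrachloride, a solvent that injures hepatocytes. The libraries were 3 controls and 5 with exposure to a static magnetic field (SMF), grouped by their titles. Droplet libraries of the 3' ends of transcripts were prepared with unique molecular identifiers (UMIs) after removal of erythrocytes; debris and dead cells were removed or not as decided for each preparation, and the labels do not say for which. The labels name the SeekOne droplet kit in the protocol and another droplet system in the description. The design text of the series speaks of a hepatocyte cell line, whereas every sample is labelled as liver tissue and the matrices hold liver and blood cell classes, so the sample labels were followed. The labels do not state that each library came from a separate mouse, so p-values measure the spread between these samples.

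The authors deposited one matrix per library whose values are UMI counts, whole numbers per gene and cell barcode, and hold no barcode under 500 UMIs. Their reads were mapped to GRCm 39; the aligner and the counting program are not given in the sources used here. The matrices held 28158 genes and 60272 barcodes. Total UMIs per library were 24456643, 57512134 and 36644264 in controls 1, 2 and 3, and 23826944, 30304686, 23297219, 31107304 and 57387987 in SMF 1, 2, 3, 4 and 5. A gene's sum over a class carries the counting error of its UMIs, and the spread between libraries was larger than counting error in all 28 pairs of libraries, with a chi-square per degree of freedom of 18.5 to 1878.

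Cells with at least 500 UMIs, at least 200 genes and at most 30% of UMIs from the 13 mitochondrial protein genes were kept. Doublets were called per library with Scrublet in scanpy 1.11.5 and removed (2045 barcodes). In SMF 3 the automatic threshold called 1 barcode, so 0.223, the median threshold of the other libraries, was used there and called 183. In all, 57121 cells were kept. Counts were scaled to 10000 per cell and log-transformed; 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1 gave 26 clusters, with no batch integration. A cluster took the name of a cell type when at least 3 markers, making up at least 1 in 3 of its list, were found in at least 10% of the cells at 2 or more times the mean of the other cells of the same libraries. It stayed unnamed when its 10 leading genes held more markers of another type, when another of the 21 marker lists had as many markers and under 5 of its own were leading genes, or when its UMIs were low and under 2 were. The marker lists were fixed beforehand, and this naming rule was set after seeing the data. This named 20 clusters and left 6 unnamed; unnamed cells were kept in the denominators and clustered again for description.

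Counts were summed per library and class over libraries with at least 10 cells, and over all cells. Differences between SMF and control were tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM factors, filterByExpr) and called at an adjusted p under 0.05 (Benjamini-Hochberg within the class). Counts scaled to a common depth (CPM) use the TMM effective library sizes. Over 39 gene lists fixed beforehand, with at least 5 tested members, limma 3.58.1 camera was run with a preset correlation of 0.01, adjusted over the lists of the class. Shares of cells and of mitochondrial UMIs were compared with exact two-sided permutation tests of the mean difference over all 56 splits of the 8 libraries, whose smallest possible p is 0.0179. The groups, lists, markers, filters, tests, most of the alternatives and the rule for named genes were fixed before the data were examined. Under that rule the text names the largest changes among called genes, up to 5 genes with the smallest p in a class where fewer than 5 pass, up to 4 members with the smallest p of each list past the threshold, and 21 fixed genes.

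The alternatives fixed beforehand were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, the replicate number as a block, stricter and looser cell filters, doublets kept, Leiden resolution 0.5, genes left out that were at under 0.1 of their level in another class, at least 30 cells, camera with an estimated correlation, fry, and leaving out each library. Chosen after seeing the data were the share among cells of named classes and 3 alternatives for a division of the libraries seen in the counts themselves and absent from the labels: libraries rich or poor in Cdk8 UMIs, used as a covariate (also with an estimated correlation and with fry), or each kind fitted alone. Within the 3 Cdk8-poor libraries the lone SMF library, and within the 5 Cdk8-rich libraries the lone control, is assumed to vary like the other group.

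The tests were checked on simulated data with 200 changed genes per class, drawn from the more highly expressed genes. With the spread of the pooled libraries, edgeR recovered 1% of 2-fold changes in B cell-like, 0% in T cell-like, 4% in natural killer cell-like, 1.02% in neutrophil-like, 0% in plasma cell-like and 0% in plasmacytoid dendritic cell-like cells. In the same order it recovered 49%, 53%, 51%, 2.02%, 6.10% and 22.2% of 4-fold changes. DESeq2, whose false calls were not counted, recovered 82%, 86%, 93%, 63.3%, 64.6% and 61.25% of these. With the library kind removed from the spread, edgeR recovered 88%, 82%, 81%, 31.3%, 25.5% and 30% of 2-fold changes, and between 94.4% and 100% of 4-fold changes. The simulated counts held no kinds and were fitted without the kind as a covariate. They therefore do not give the recovery of the kind-adjusted test. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19 and matplotlib 3.10.9 were used. Gene positions, and GC content and exon numbers for 1 check, came from an annotation of the earlier mouse build.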

Results

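The series title names a static magnetic field (SMF), liver injury, calcium influx and cellular respiration. Liver cells of mice given carbon tetrachloride, a hepatotoxin used to model liver injury, were profiled by droplet single-cell RNA sequencing in 3 control and 5 SMF libraries. The deposited matrices held 5592, 9556 and 7640 barcodes in the controls and 6170, 5127, 6941, 5807 and 13439 in the SMF libraries. The median number of UMIs per barcode was 3664.5, 5307 and 4153 in the controls and 3225, 5029, 2330, 4391 and 3579 in the SMF libraries. After filtering, 57121 cells were kept. The strength of the field, its duration and the dose of carbon tetrachloride were not in the labels used here.

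The kept cells were mostly lymphocytes. B cell-like cells, which carried Cd79a and Ms4a1, made up 22140 cells (38.8%), and T cell-like cells, with Cd3e and Trac among their markers, 19212 (33.6%). Cells like natural killer cells or type 1 innate lymphoid cells, led by the killer-cell genes Gzma and Prf1, numbered 5255 (9.20%) and are called natural killer cell-like below. Neutrophil-like cells, led by S100a8 and Ngp, numbered 1371 (2.40%), and erythroid-like cells, led by the globin genes Hbb-bs and Hba-a1, also 1371 (2.40%). Plasma cell-like cells, led by Jchain and Mzb1 of antibody secretion, numbered 318 (0.557%), and plasmacytoid dendritic cell-like cells, led by Siglech, 307 (0.537%). The plasma cell-like cluster also had 14 of the 15 cycling cell markers past the naming threshold, against 10 plasma cell markers, and took its name through its leading genes. No main cluster was hepatocyte-, stellate cell- or endothelial-like. Unnamed cells took 8.29% ± 5.08 (SD, n = 3) of the control and 14.2% ± 16.3 (SD, n = 5) of the SMF cells (exact permutation p = 0.804), with 42.8% in SMF 3, where 2751 cells with few UMIs formed most of 1 cluster.

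To ask whether SMF went with another make-up of the liver's immune cells, the share of each class was compared. Natural killer cell-like cells made up 12.0% ± 2.7 (SD, n = 3) of control and 8.70% ± 3.95 (SD, n = 5) of SMF cells, a difference of -3.33 percentage points (exact permutation p = 0.232). The shares of B cell-like cells were 38.2% ± 8.95 and 39.4% ± 6.30, and those of T cell-like cells 34.7% ± 4.22 and 33.3% ± 8.57 (exact permutation p = 0.821 for each). Neutrophil-like cells made up 2.48% ± 1.63 and 2.36% ± 0.965 (exact permutation p = 0.857), and plasma cell-like cells 0.448% ± 0.189 and 0.536% ± 0.331 (0.714 by the same exact test). Plasmacytoid dendritic cell-like cells made up 0.410% ± 0.239 and 0.532% ± 0.221 (exact permutation p = 0.518). Adjusted over the 6 classes, each p of this permutation test was 0.857, so no share differed by more than the pooled spread between libraries. That spread includes the library kinds described next, and 3 against 5 libraries cannot exclude a difference. The edgeR test on cell numbers gave an adjusted p of 0.909 for each class. Within the library kinds described next, the difference for natural killer cell-like cells was -5.19 points in the Cdk8-rich and -6.77 in the Cdk8-poor libraries. For B cell-like cells it was -4.58 and 3.83, and for T cell-like cells -0.656 and -0.0103. Neutrophil-like cells differed by -1.61 and 1.05; the latter was -0.155 with the stricter cell filter and -0.289 at Leiden resolution 0.5. Among them, 1 cluster of 208 cells with a median of 700 UMIs held 184 cells of SMF 5. Plasma cell-like cells differed by -0.0200 and 0.540, and plasmacytoid dendritic cell-like cells by 0.260 and 0.360.

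**Figure D1:**
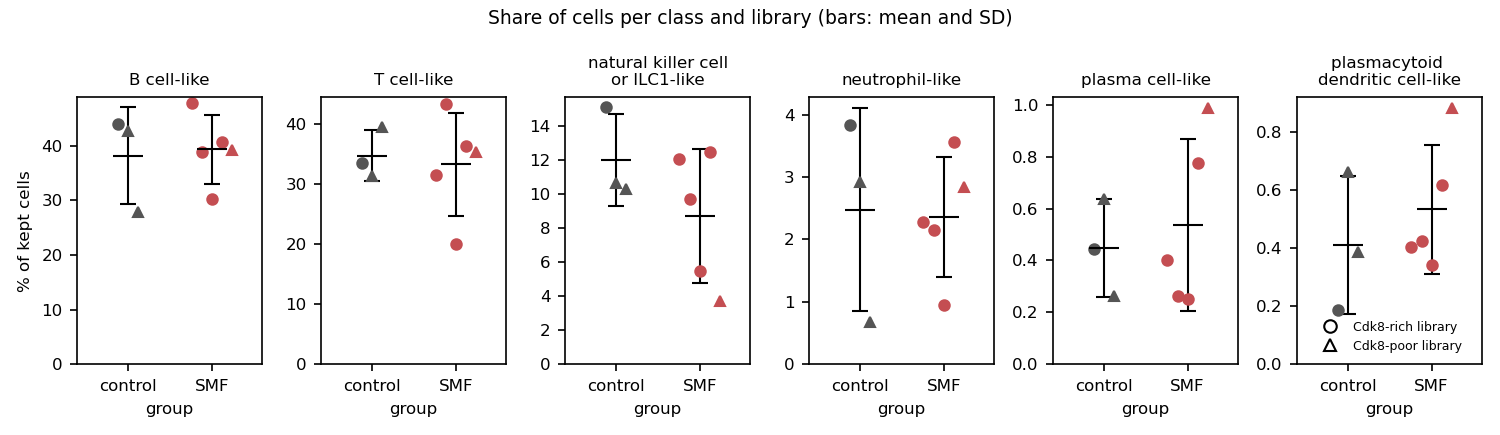
Share of kept cells (percent) in each of the 6 compared cell classes, each point 1 library, with the mean and SD of the 3 control and 5 SMF libraries. The groups overlap in every class, with natural killer cell-like cells at 12.0% ± 2.7 in control and 8.70% ± 3.95 in SMF.

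The libraries fell into 2 kinds that cross the groups. In control 1 and SMF 1, 2, 3 and 4, Cdk8, which encodes a kinase of the Mediator complex, took 7.14% to 10.7% of all UMIs, against 0.190% to 0.233% in controls 2 and 3 and SMF 5. Together with Camk1d, a calcium/calmodulin-dependent kinase gene, Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, Cmss1 and Peak1, these genes took 21.1% to 30.6% of UMIs in the Cdk8-rich and 0.764% to 1.13% in the Cdk8-poor libraries. Ribosomal protein genes took 2.04% to 2.20% against 15.9% to 24.4%, mitochondrial genes 0.456% to 0.647% against 1.45% to 2.73%, and hemoglobin genes 0.00701% to 0.0518% against 1.65% to 14.2%. The main clustering named erythroid-like cells in the Cdk8-poor libraries alone, and clustering the unnamed cells again named 178 in the Cdk8-rich libraries, so the share and the genes of that class were not compared. EdgeR on its cell numbers gave a log2 fold change of -1.74 (adjusted p = 0.909). T, B, natural killer and neutrophil-like cells of the 2 kinds lay in different clusters, and those of control 2, apart from neutrophil-like cells, lay apart as well. Plasma cell-like and plasmacytoid dendritic cell-like cells each formed 1 cluster. The Cdk8-poor libraries were uneven among themselves. The chi-square per degree of freedom was 611 between controls 2 and 3 and 530 between control 2 and SMF 5. Between control 3 and SMF 5 it was 180. Values adjusted for the kind or taken within the Cdk8-poor libraries still hold this difference of control 2. Since 1 of 3 controls and 4 of 5 SMF libraries were Cdk8-rich, many of the values below are also given with the kind as a covariate or within each kind, both chosen after seeing the data.

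**Figure D2:**
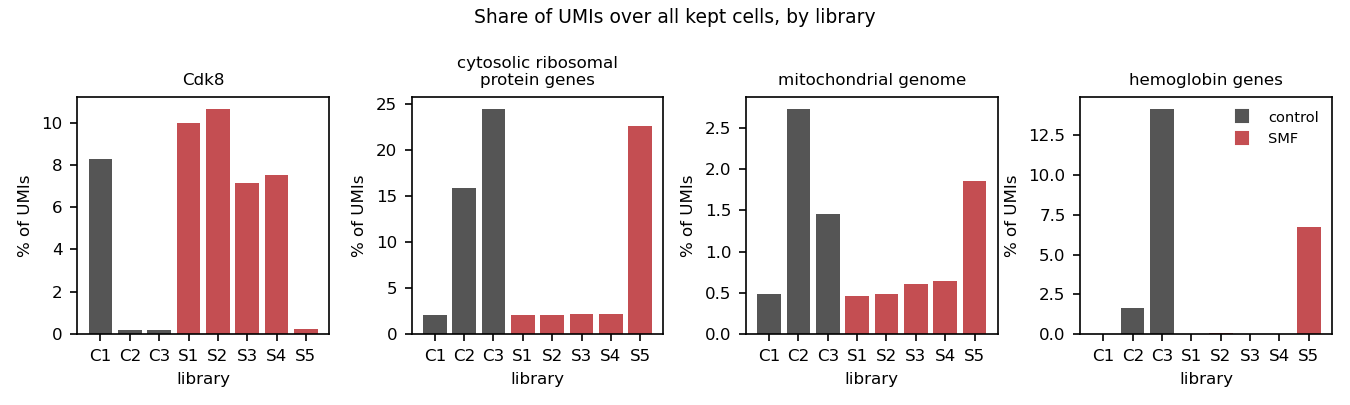
Percent of UMIs from Cdk8, ribosomal protein, mitochondrial and hemoglobin genes in each of the 8 libraries, with control and SMF libraries in different colours. Control 1 lies with SMF 1 to 4 and SMF 5 with controls 2 and 3 in every panel, with ribosomal protein genes at 2.04% to 2.20% and 15.9% to 24.4%.

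Cellular respiration was examined through mitochondrial transcripts and the genes of the respiratory chain. Transcripts of the mitochondrial genome took 1.65% ± 1.12 (SD, n = 3) of the UMIs of control and 0.839% ± 0.647 (SD, n = 5) of SMF T cell-like cells, and 1.84% ± 1.29 and 0.883% ± 0.662 in B cell-like cells (exact permutation p = 0.339 and 0.357). The list of cytosolic ribosomal proteins was lower in SMF in all 6 classes, with all 44 members negative in each and median log2 fold changes of -1.21 to -0.94. This call and those that follow were lost in every class with an estimated correlation (adjusted p = 0.620 or higher). Lower too were the 13 protein genes of the mitochondrial genome (medians -0.91 to -0.68), the nuclear genes of complex I, the entry point of electrons from NADH (-0.85 to -0.77), and those of complexes II to V (-1.05 to -0.70). With the library kind as a covariate these medians were 0.07 to 0.56, -0.13 to 0.06, 0.05 to 0.26 and 0.03 to 0.28, and the decrease did not hold in any class. Within the Cdk8-poor libraries the mitochondrial genome had medians of -0.40 to -0.19, and within the Cdk8-rich libraries -0.10 to 0.38. The pooled medians also moved when single libraries were left out, which changes the mix of kinds. Without SMF 5 all SMF libraries left are Cdk8-rich, and without control 1 all controls left are Cdk8-poor. Without SMF 5 they were -2.82 to -2.73, -1.44 to -1.01, -1.90 to -0.67 and -2.17 to -1.49 in the same order, and without control 1 -1.73 to -1.47, -1.36 to -1.11, -1.34 to -1.17 and -1.64 to -1.19. Without control 3 they were -0.28 to -0.0019, -0.82 to -0.58, -0.27 to -0.070 and -0.22 to -0.12, and passed in 5, 5, 1 and 2 of the 6 classes. Without control 2 the mitochondrial genome had -0.70 to -0.56.

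EdgeR called none of the single genes of these lists. In T cell-like cells, mt-Nd4l, a complex I subunit of the mitochondrial genome, had a log2 fold change of -0.99 ± 0.30 (SE), from 293 ± 112 CPM (SD, n = 3) to 147 ± 35.4 (SD, n = 5). Cox6a1 of complex IV had -1.24 ± 0.80, the complex III subunit gene Uqcrfs1 -0.89 ± 0.59, Ndufs4 of complex I -0.30 ± 0.18, and Rpl35 of the large ribosomal subunit -1.41 ± 0.69 (adjusted p = 0.846 for each). With 1 library left out, mt-Nd4l ranged from -1.27 to -0.75 and Cox6a1 from -2.20 to -0.41. Uqcrfs1 then ranged from -1.54 to -0.32, Ndufs4 from -0.45 to -0.16 and Rpl35 from -2.05 to -0.89. Within the Cdk8-rich libraries mt-Nd4l had -0.23, Cox6a1 -0.26, Uqcrfs1 -0.33, Ndufs4 0.02 and Rpl35 0.06. Within the Cdk8-poor libraries they had -1.10, -0.16, 0.01, -0.28 and -0.64, in the same order, and with the kind as a covariate mt-Nd4l had -0.62 ± 0.27 (SE). In natural killer cell-like cells mt-Nd4l had -1.06 ± 0.29, with all 5 SMF libraries below all controls (edgeR adjusted p = 0.874). The separation was narrow, with SMF 2 at 120.2 and control 1 at 121.0 CPM. Its log2 fold change there was -0.29 within the Cdk8-rich and -1.26 within the Cdk8-poor libraries, and -0.70 with the kind as a covariate. Camera's adjusted p over the lists was 1.58e-11 to 1.13e-08 for the ribosomal list and 1.36e-05 to 0.00208 for the mitochondrial genome over the classes. No list of any kind passed with an estimated correlation, where the lists that passed had an adjusted p of 0.620 to 0.895. Neither over all genes nor adjusted over the list alone did edgeR call any member (0 genes). The mitochondrial share was 1.26% ± 0.892 in control and 0.609% ± 0.50 in SMF natural killer cell-like cells, and 0.494% ± 0.348 and 0.239% ± 0.15 in neutrophil-like cells (exact permutation p = 0.339 and 0.25). It was 1.88% ± 1.11 and 0.955% ± 0.423 in plasma cell-like cells, and 2.36% ± 1.52 and 1.09% ± 0.843 in plasmacytoid dendritic cell-like cells (exact permutation p = 0.0893 and 0.268). Over all cells it was 1.56% ± 1.13 and 0.810% ± 0.591 (exact permutation p = 0.339), and each adjusted p was 0.357. The differences moved when single libraries, and with them the mix of kinds, were left out. Without control 2 the differences were -0.253 points in T cell-like cells, -0.329 in B cell-like cells and -0.157 over all cells. Without control 1, where only Cdk8-poor controls are left, they were -1.37, -1.62 and -1.28. Over the 6 classes they ran from -0.587 to -0.0882 without control 2 and from -2.09 to -0.435 without control 1. Within the Cdk8-rich libraries SMF was higher by 0.000636 to 0.085 percentage points over the 6 classes, and within the Cdk8-poor libraries the difference lay between -0.742 and -0.177. Among the latter SMF 5, at 1.86% over all cells, lay between control 2 (2.73%) and control 3 (1.45%).

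**Figure D3:**
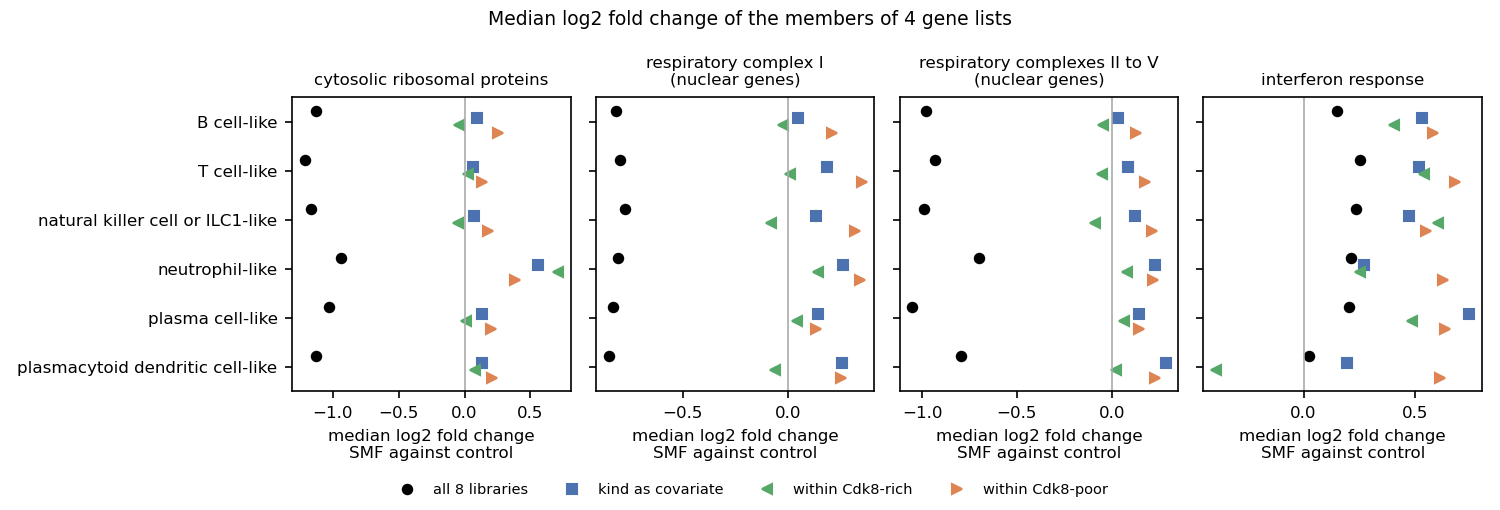
Median log2 fold change (SMF against control) of 4 gene lists in each cell class, over all 8 libraries, with the library kind as a covariate, and within each kind. The ribosomal and the 2 nuclear respiratory lists lie at -1.21 to -0.70 over all libraries and at 0.03 to 0.56 with the kind as a covariate.

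Calcium influx was examined through the genes of calcium entry and handling and those of calcium-dependent signalling. Orai1, the pore of the store-operated calcium channel, was measured at 168 ± 73.8 CPM (SD, n = 3) in control and 90.1 ± 8.35 (SD, n = 5) in SMF T cell-like cells, a log2 fold change of -0.90 ± 0.27 (SE), and at 274 ± 106 and 147 ± 14.8 CPM in natural killer cell-like cells, -0.90 ± 0.27. It had -0.83 ± 0.28 in B cell-like cells. None was called (adjusted p = 0.846, 0.874 and 0.837), and within the Cdk8-rich libraries the values were -0.06, -0.00 and -0.05, against -1.07, -1.54 and -0.89 within the Cdk8-poor ones. With 1 library left out, Orai1 ranged from -1.19 to -0.55, -1.19 to -0.69 and -1.08 to -0.47 in the same order of classes. In T cell-like cells Stim1, the calcium sensor that opens Orai1, had -0.15 ± 0.16 and the mechanosensitive channel gene Piezo1 0.03 ± 0.26. The mitochondrial uniporter gene Mcu had 0.15 ± 0.27 and the endoplasmic reticulum pump gene Atp2a2 0.04 ± 0.25. With the library kind as a covariate Piezo1, Mcu and Atp2a2 had -0.33, -0.17 and -0.25. Over the 6 classes the median of the calcium entry list was -0.19 to 0.03 (adjusted p = 0.713 or higher) and that of calcium-dependent signalling -0.21 to -0.00 (0.0517 or higher), so neither list passed the threshold. With the kind as a covariate, calcium-dependent signalling was lower in plasma cell-like cells (median -0.23, adjusted p = 0.0152). In that fit 0 lists passed in any class with an estimated correlation (smallest adjusted p = 0.137).

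Interferon-stimulated genes, which are induced in antiviral and inflammatory states, were higher in SMF in T cell-like and natural killer cell-like cells. In T cell-like cells 24 of 29 members were positive (median 0.25, adjusted p = 2.19e-04), and in natural killer cell-like cells 18 of 26 (median 0.24, adjusted p = 0.0110). With an estimated correlation the adjusted p was 0.895 and 0.679, and neither call held without control 1 (medians 0.086 and 0.12) or without SMF 5 (0.17 and 0.15). Without control 2 the 2 medians lay between 0.076 and 0.14 and without control 3 between 0.39 and 0.61, and without SMF 4 the lower was 0.15. Ifit3, an inhibitor of viral replication, was at 1.80 ± 0.965 CPM (SD, n = 3) in control and 5.29 ± 1.34 (SD, n = 5) in SMF T cell-like cells, with all 5 SMF libraries above all controls and a log2 fold change of 1.55 ± 0.40 (SE). Ifih1, a sensor of viral RNA, had 0.73 ± 0.23. In natural killer cell-like cells Ifit2 went from 4.09 ± 1.49 to 12.0 ± 3.81 CPM (1.57 ± 0.40), and Oas1a had 1.26 ± 0.42. None of these 4 genes was called (adjusted p = 0.846 and 0.874 by class). The list's median was 0.54 within the Cdk8-rich and 0.68 within the Cdk8-poor libraries in T cell-like cells, and 0.60 and 0.55 in natural killer cell-like cells. With the kind as a covariate it was 0.52 and 0.47, where with an estimated correlation the adjusted p was 0.766 and 0.80. In that fit immediate early and dissociation stress genes were higher too, in all 6 classes (medians 0.55 to 2.34), and 0 lists passed with an estimated correlation.

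EdgeR called no single gene in any class; its counts at an unadjusted p and the calls of DESeq2 are given below. Cebpb, a transcription factor of myeloid and inflammatory programmes, was lower in SMF. In neutrophil-like cells it stood at 306 ± 127 CPM (SD, n = 3) against 36.4 ± 23.0 (SD, n = 5), a log2 fold change of -3.05 ± 0.55 (SE, edgeR adjusted p = 0.9995). In natural killer cell-like cells it stood at 15.3 ± 6.51 against 2.15 ± 0.254, with -2.84 ± 0.32 (edgeR adjusted p = 0.130). In both classes all 5 SMF libraries lay below all controls, within the Cdk8-rich (-2.55 and -2.56) and the Cdk8-poor libraries (-2.61 and -2.80) alike. Its level in natural killer cell-like cells was under 0.1 of that in another class. Frat2, which encodes a GSK3-binding protein of the Wnt pathway, had -1.61 ± 0.29 in T cell-like and -1.83 ± 0.33 in natural killer cell-like cells. Jund, an AP-1 subunit gene, had -1.37 ± 0.29 in T cell-like cells, and Spry2, an inhibitor of receptor tyrosine kinase signalling, -1.14 ± 0.24. Arf6, a small GTPase gene of membrane traffic, had -1.57 ± 0.33 in natural killer cell-like cells (74.5 ± 1.58 against 25.1 ± 12.2 CPM) and -1.38 ± 0.39 in plasma cell-like cells. Dusp2, a phosphatase gene that restrains MAP kinases, had -0.99 ± 0.22 in B cell-like cells, and Bub1b of the mitotic checkpoint 1.48 ± 0.29 in natural killer cell-like cells. With the kind as a covariate Frat2 had -1.37 and -1.50, Jund -1.04, Spry2 -0.91, Arf6 -1.37 and -1.09, Dusp2 -0.87 and Bub1b 1.40. Within the Cdk8-rich and the Cdk8-poor libraries Arf6 had -1.88 and -0.77 in natural killer cell-like cells, and Dusp2 -1.28 and -0.35.

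Other genes with the smallest p had the following log2 fold changes. In B cell-like cells they were Sft2d3 (-2.06), Prkar2a (-0.76), Rnf11 (-0.65) and Rubcn (0.61), and in T cell-like cells Meis1 (-2.22) and Fap (2.35). With the kind as a covariate these had -1.68, -0.77, -0.64, 0.53, -1.92 and 1.99. Meis1 and Fap were at low levels in T cell-like cells. Meis1 was at 2.30 CPM in control and 0.486 in SMF, and Fap at 0.542 and 2.88. In neutrophil-like cells Krt83 had -1.19, Pknox1 1.04, Chaf1b 1.74 and Tmem222 1.42, and in natural killer cell-like cells Hilpda had -1.65. With the kind as a covariate these had -0.96, 0.87, 1.48, 1.37 and -1.06, and Hilpda had -0.38 within the Cdk8-rich and -1.99 within the Cdk8-poor libraries. In plasmacytoid dendritic cell-like cells Lifr, the receptor of leukemia inhibitory factor, was at 92.0 ± 26.0 CPM (SD, n = 3) in control and 233 ± 21.8 (SD, n = 5) in SMF (1.38 ± 0.27 SE), and Daam1 had 1.63 and Heatr5a -1.99. Kind-adjusted, Lifr had 1.36 (adjusted p = 0.0369, called), Daam1 1.21 and Heatr5a -1.87. In plasma cell-like cells a heavy-chain and a kappa light-chain V segment of antibody genes had 6.39 ± 1.62 and 6.15 ± 1.72 (SE), and kind-adjusted 4.83 and 5.76. Antibody V segments have near-identical copies among which reads are hard to place. The light-chain segment ran from 0 CPM in control 3 to 4738 in SMF 2. The libraries held only 13 to 120 plasma cell-like cells each, so a few cells of 1 clone may set these values, which was not tested. Ralgds had 1.70 and Bard1 1.69 there, kind-adjusted 1.04 and 1.13, and within the Cdk8-poor libraries 0.36 and 0.37. Cebpb lies on chromosome 2 (167688915 to 167690418), Frat2 on chromosome 19 (41845972 to 41848132), Arf6 on chromosome 12 (69372150 to 69373783) and Orai1 on chromosome 5 (123015074 to 123030456) of the earlier mouse build GRCm38.

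At an adjusted p under 0.05, edgeR called 0 genes in each class and over all cells summed. Unadjusted p was under 0.05 for 307 of 11635 tested genes in B cell-like, 484 of 12692 in T cell-like and 348 of 10288 in natural killer cell-like cells. It was under 0.05 for 107 of 5300 in neutrophil-like, 70 of 5197 in plasma cell-like and 153 of 4570 in plasmacytoid dendritic cell-like cells, and for 551 of 15091 over all cells. DESeq2 called Cebpb, Frat2 and Jund in natural killer cell-like cells (3 genes), Cebpb in neutrophil-like (1), Frat2 in T cell-like (1) and the 2 antibody V segments above in plasma cell-like cells. It called 0 in B cell-like and plasmacytoid dendritic cell-like cells. With the library kind as a covariate, edgeR called 1 gene in B cell-like (Gm20481), 1 in neutrophil-like (Cebpb), 1 in plasma cell-like (Fos) and 28 in plasmacytoid dendritic cell-like cells. It called 0 in T cell-like and natural killer cell-like cells. Gm20481 and Fos are outside the rule for named genes and were chosen after their values were seen. Without SMF replicate 5, 210 genes were called in plasmacytoid dendritic cell-like cells and 1, Arf6, in natural killer cell-like cells. Of the 210, 183 were lower in SMF. SMF 5 is the only Cdk8-poor SMF library, so that fit sets Cdk8-rich SMF libraries against mostly Cdk8-poor controls. The split along the kind called 1535 genes in plasmacytoid dendritic cell-like cells, so the 210 cannot be read as effects of the field. Among the 21 fixed genes, 14 were tested in T cell-like cells and 19 over all cells, and 0 passed. Tnf, the inflammatory cytokine, had 0.58 ± 0.22 (SE) in T cell-like cells and Sod2, the mitochondrial superoxide dismutase, -0.55 ± 0.33 in neutrophil-like cells (kind-adjusted 0.69 and -0.82).

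**Figure D4:**
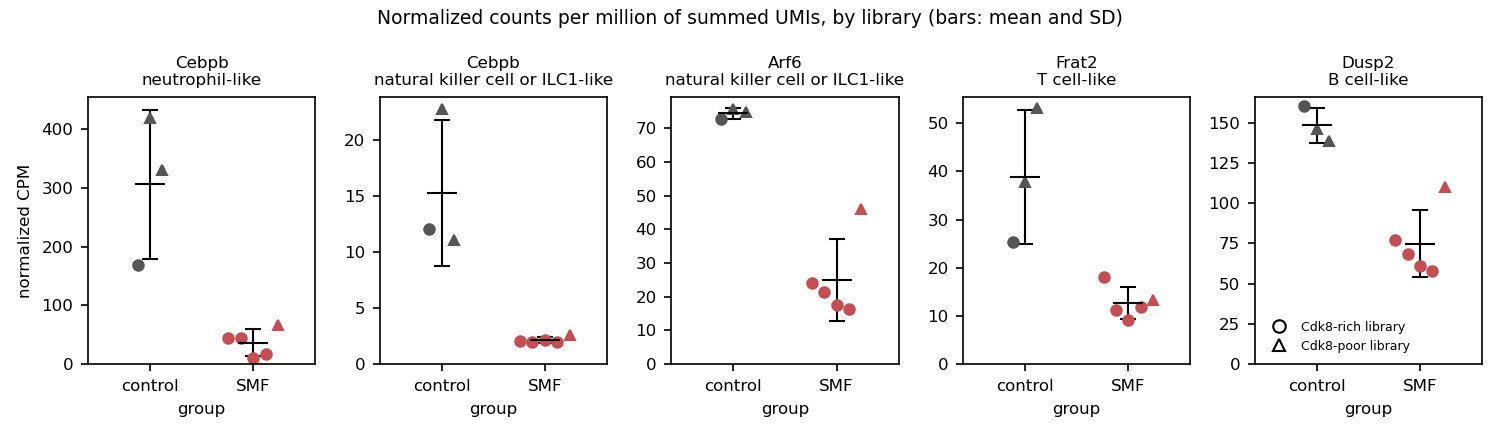
CPM of 4 named genes in each library, by cell class, with the mean and SD of the 3 control and 5 SMF libraries and the library kind shown by marker. Cebpb lies at 306 ± 127 CPM in control and 36.4 ± 23.0 in SMF neutrophil-like cells, and all SMF libraries lie below all controls in each panel.

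Lists of blood cell programmes and of transcripts used to check for free RNA were lower in SMF as well. Neutrophil maturation and granule genes were lower in all 5 classes tested (medians -1.35 to -0.43), though only neutrophil-like cells are of that cell type. Neutrophil transcripts used to check for free RNA were lower in 4 (-1.95 to -1.06), among them neutrophil-like cells, where they are the cells' own. These and all other list calls of this paragraph were lost with an estimated correlation. Retnlg, a mature neutrophil gene, had a log2 fold change of -1.85 ± 0.99 (SE) in neutrophil-like cells. Kind-adjusted it had -0.54, within the kinds -0.49 (Cdk8-rich) and -0.68 (Cdk8-poor), without SMF 5 -3.26 and without control 3 -1.39. Genes of cytotoxicity and T cell activation were lower in 4 of 6 classes, with medians of -1.37 in B cell-like, -0.35 in T cell-like, -0.34 in natural killer cell-like and -0.58 in plasma cell-like cells; with an estimated correlation it passed in 0. Among its members, Tnfrsf9, the costimulatory receptor 4-1BB gene, had -0.66 ± 0.19 in T cell-like and -0.87 ± 0.24 in natural killer cell-like cells, and Icos, another costimulatory receptor gene, -0.60 ± 0.21 in T cell-like cells (kind-adjusted -0.54, -0.85 and -0.38). In B cell-like cells, where the list fell most, Tnfrsf9 was at 5.62 CPM in control and 1.87 in SMF. In natural killer cell-like cells it was at 280 and 153. Free RNA from other cells may thus enter the B cell-like median, which was not tested. The chemokine gene Xcl1 had -1.78 ± 0.67 in natural killer cell-like cells, where it had -0.07 within the Cdk8-rich and -1.13 within the Cdk8-poor libraries. Nrf2 targets of the oxidative stress response were lower in 4 of 6 classes (-0.51 in B cell-like, -0.40 in T cell-like, -0.27 in neutrophil-like and -0.51 in plasma cell-like cells), among them the superoxide dismutase gene Sod1, with -1.32 ± 0.54 in T cell-like cells (kind-adjusted -0.30). Without control 2 the neutrophil maturation medians were -0.47 to 0.13 (1 of 5 classes passed) and those of neutrophil transcripts -0.99 to -0.11 (1 of 4). Without SMF 5 they were -1.89 to -0.68 (2 of 4) and -3.51 to -2.17 (3 of 3). Without control 1 they were -1.68 to -0.73 (5 of 5) and -2.61 to -1.52 (4 of 4), and without control 3 -1.50 to -0.31 (3 of 5) and -2.33 to -0.48 (4 of 4). Neutrophil maturation passed in 4 of 5 without SMF 1. Cytotoxicity passed in 3 of 4 classes without control 2 (-1.02 to -0.18), without control 3 (-0.87 to -0.042) and without SMF 5 (-1.95 to -0.50). Nrf2 targets passed in 0 of 4 without control 3 (-0.11 to -0.017) and in 3 of 4 without control 2, SMF 1 or SMF 4.

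Hepatocyte transcripts, read as free RNA in lymphocytes, were lower in both classes tested (-0.76 in B cell-like and -1.13 in T cell-like cells), as were secreted plasma proteins of hepatocytes (-0.77 and -0.99). An estimated correlation ended these calls and the other list calls of this paragraph. Apoa2, an apolipoprotein gene, was at 2.33 ± 2.08 CPM (SD, n = 3) in control and 0.377 ± 0.663 (SD, n = 5) in SMF T cell-like cells. Lymphocyte and plasma cell transcripts were lower in 3 of 4 classes, and antigen presentation in plasma cell-like cells (median -0.41). Those 3 classes were B cell-like, natural killer cell-like and plasma cell-like cells, which carry members of the lymphocyte and plasma cell list themselves. Hepatocyte transcripts and secreted plasma proteins each passed in 1 of 2 classes without control 2, without control 3 and without SMF 5. Without control 3 their medians were -0.60 to -0.53 and -0.52 to -0.44, and without SMF 5 -1.90 to -1.85 and -1.77 to -1.01. Lymphocyte and plasma cell transcripts passed in 0 of 3 classes without control 3 (-0.72 to -0.36) and 1 of 3 without control 2. Antigen presentation did not pass without control 3 (0.12), SMF 1 (-0.28) or SMF 2 (-0.27), and was at -1.12 without SMF 5. With the library kind as a covariate, the medians were -0.25 to -0.01 for neutrophil maturation, -0.25 to -0.14 for neutrophil transcripts, -0.33 to 0.41 for cytotoxicity, 0.02 to 0.39 for Nrf2 targets and -0.10 to -0.06 for hepatocyte transcripts. None of these lists then passed. In all, 51 of 178 tests of a list in a class passed. With an estimated correlation 0 passed, and with fry 0 passed (smallest adjusted p = 0.207). In 0 of the 51 did the median, the mean and the test differ in sign; over all 178 they did in 30.

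The remaining lists passed in 0 of the classes tested. In energy metabolism the medians were -0.06 to 0.18 for the tricarboxylic acid cycle, -0.14 to -0.04 for mitochondrial biogenesis and dynamics, -0.25 to 0.17 for fatty acid oxidation and -0.02 to 0.17 for glycolysis and hypoxia. Immediate early and dissociation stress genes had medians of 0.06 to 0.96, and endoplasmic reticulum stress -0.06 to 0.19. The list of p53, apoptosis and senescence had -0.04 to 0.42, the cell cycle -0.07 to 0.37, iron handling and ferroptosis -0.22 to 0.02, and the acute phase response -0.37 to 0.21. Inflammatory cytokines and chemokines had -0.34 to 0.30, phagocytosis and efferocytosis -0.44 to 0.08, scar-associated and lipid-handling macrophage genes -0.29 to 0.20, and erythrocyte transcripts -1.52 to -0.18. Lists of cells absent from the named classes were tested on the few members detected in blood cell classes. Stellate cell activation and matrix had -0.11 to 0.23 and stellate cell quiescence -0.31 to -0.29. Sinusoidal endothelial identity had -0.38 to 0.12, endothelial activation and angiogenesis 0.03 to 0.23, and Kupffer cell identity 0.12 in the 1 class tested. Of hepatocyte functions, xenobiotic metabolism had -0.10 to 0.09, pericentral genes -0.18 to -0.03 and periportal genes -0.17 to 0.12. Urea cycle, gluconeogenesis and amino acid catabolism had -0.10 to 0.09, and bile acid and cholesterol metabolism 0.00 to 0.27.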

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

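The tests against the library kind and against a few genes taking many of the counts were chosen only after the results they bear on had been seen, as was the set of 4 genes in the pattern of natural killer cell-like cells; the other tests here were chosen before their result was seen. Among the 5 SMF libraries, 38 of 96 values (39.6%) had a library far from the others, where chance finds about 1 in 20 groups; 36 of the 38 were SMF 5, the only Cdk8-poor SMF library, 1 was SMF 3 and 1 SMF 4. The group of 3 controls is too small for this test.

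Ribosomal and respiratory genes were lower in SMF in all 6 classes, calls that were lost with an estimated correlation (0 lists passed). The library kind fits this pattern: with the kind as a covariate, the ribosomal median lay within 0.2 of 0 in 5 of the 6 classes. The exception was neutrophil-like cells, at 0.56. The mitochondrial genome had -0.13 to 0.06, yet within the Cdk8-poor libraries it stayed lower in all 6 classes (medians -0.40 to -0.19). That comparison sets SMF 5 alone against controls 2 and 3. Over all cells the mitochondrial share of SMF 5, 1.86%, lay between those of control 2 (2.73%) and control 3 (1.45%). A few genes taking many of the counts would lower all other genes alike and are argued against, since the 4 list medians lay below the median of all tested genes in each class, with differences of -1.22 to -0.70. A candidate explanation is therefore that the unequal mix of library kinds lowered these lists, for the mitochondrial genome perhaps in part; what made the kinds differ stays open, as the labels give no batch. A field effect on respiration within the kinds rests on 1 control in one kind and 1 SMF library in the other, and stays open.

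Interferon-stimulated genes were higher in SMF T cell-like cells, with a kind-adjusted median of 0.52. Any single one of 6 libraries is argued against as the source, since the lowest median with 1 of them left out was 0.38 (without control 2); for control 1 and SMF 5, each alone in its kind and group, this stays open. Free RNA from other cells is argued against by a median of 0.50 over the 15 members whose level was at least 0.5 of that in any other class. The splits within the kinds are too few for a share under 0.05 (1 of 15 reached the real value; the highest other was 0.44). A response to the field may underlie it, though with an estimated correlation the kind-adjusted adjusted p was 0.766 and with fry 0.682. The injury itself was shared by both groups, and whether its severity differed was not tested. Differences between mice unrelated to the field stay open. Handling does too, since immediate early and dissociation stress genes were higher in the same fit (medians 0.55 to 2.34 over the 6 classes).

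Cebpb, Frat2, Arf6 and Spry2 were lower in SMF natural killer cell-like cells, with a pooled median log2 fold change of -1.70, though edgeR called none (adjusted p = 0.130 for Cebpb and 0.874 for the others). The kind-adjusted median was -1.43, so these 4 genes did not simply follow the library kind. They were picked for a small pooled p, in these or in T cell-like cells. Genes that follow the kind spread widely within the groups and seldom have one, so the choice largely fixed this outcome. Hilpda, also lower and among the genes with the smallest p here, had -0.38 within the Cdk8-rich and -1.99 within the Cdk8-poor libraries. GC content and few introns are argued against, since the 796 other tested genes with at most 2 exons and a similar GC content had a kind-adjusted median of 0.057 (quartiles -0.18 and 0.30), with 98.6% of tested genes matched to the annotation. An effect of the field, differences in handling between samples, and for Cebpb free RNA from neutrophil-like cells, where it was lower too, may underlie it; none of these was tested. Genes picked for their small p overstate their fold.

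Unnamed cells made up 42.8% of SMF 3, against 5.21% to 12.0% in the other SMF libraries. SMF 5 had 13439 barcodes and 57387987 UMIs. Its mitochondrial share of UMIs was 1.86% over all cells, against 0.456% to 0.647% in the other SMF libraries. By class it was 2.06% in B cell-like, 1.99% in T cell-like, 1.5% in natural killer cell-like, 0.497% in neutrophil-like, 1.69% in plasma cell-like and 2.59% in plasmacytoid dendritic cell-like cells. Ribosomal protein genes took 22.6% of its UMIs (others 2.05% to 2.20%) and hemoglobin genes 6.75% (others 0.0123% to 0.0518%). Albumin mRNA stood at 35.7 CPM in SMF 4, against 0.907 to 7.80 in the other SMF libraries.

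Single genes of SMF 5 stood apart as well, in CPM. In B cell-like cells Rpl35 was at 763, Rpl38 at 1858, Ndufs4 at 93.6, Cox6a1 at 118, Wfdc21 at 5.76 and Apoa1 at 2.76. In T cell-like cells Rpl35 was at 917, Rpl38 at 2310.02, Cox6a1 at 144, Uqcrfs1 at 96.6, Sod1 at 105 and Apoa2 at 1.56, all above the other SMF libraries, while Atp2a2, at 60.5, lay below them. In natural killer cell-like cells Cebpb was at 2.59, Arf6 at 46.1, Rpl35 at 469, Cox6a1 at 177 and Xcl1 at 605, above the others, and Orai1 at 120.2, below them. In neutrophil-like cells Rpl38 was at 484, Cox6a1 at 146 and Retnlg at 10818; in plasma cell-like cells Ndufb9 was at 286; and in plasmacytoid dendritic cell-like cells Rpl35 was at 639 and Atp5k at 98.6.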

How the results depend on the processing

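The 3 settings for the library kind, their further list tests and the share among named classes were chosen only after the results were seen; the other settings were fixed beforehand. Under the 3 kind settings and the share among named classes 84 list values turned, 53 fell short of the threshold and 13 held; 7 mitochondrial shares turned and 7 did not, 5 cell shares turned, 4 moved and 9 did not, and of the named genes 19 turned, 190 held and 8 became called. In simulated data with the pooled spread, edgeR recovered 2.02% of 4-fold changes in neutrophil-like and 6.10% in plasma cell-like cells. DESeq2, whose false calls were not counted, recovered 63.3% and 64.6%. At the same depth with the library kind removed from the spread, and no kind covariate in the fit, edgeR recovered 96.9% and 94.4%. Of 2-fold changes 31.3% and 25.5% were then recovered in these 2 classes and 82% in T cell-like cells; how much of that gap depth explains was not tested. Unless said otherwise, the cause of a change was not tested.

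With edgeR the real grouping called 0 genes in every class and over all cells, a count that all 56 splits reach by construction, so this comparison says nothing for or against the grouping and chance cannot be excluded. The highest other counts were 6668 in B cell-like, 6752 in T cell-like, 5035 in natural killer cell-like, 1894 in neutrophil-like, 2033 in plasma cell-like and 1535 in plasmacytoid dendritic cell-like cells and 7728 over all cells. Those counts come from the split that follows the library kind, a structure of the samples; with the kind as a covariate, the real grouping called 0 genes over all cells summed and at most 28 in a class. For gene lists chance cannot be excluded either: 23, 23, 21, 22, 17 and 37 splits reached the real 11, 11, 9, 7, 9 and 4 lists in B cell-like, T cell-like, natural killer cell-like, neutrophil-like, plasma cell-like and plasmacytoid dendritic cell-like cells, with highest others of 17, 19, 14, 14, 13 and 10. The split along the kind had 15, 15, 12, 11, 10 and 7.

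Among the settings fixed beforehand, other than leaving out libraries, 696 values of named genes kept their side of the threshold and 9 became called. Of the list calls 89 held and 108 were lost; camera with an estimated correlation passed 0 lists in B cell-like, 0 in T cell-like, 0 in natural killer cell-like, 0 in neutrophil-like, 0 in plasma cell-like and 0 in plasmacytoid dendritic cell-like cells, as did fry. DESeq2 called 1 gene in T cell-like (Frat2), 3 in natural killer cell-like (Cebpb, Frat2, Jund), 1 in neutrophil-like (Cebpb) and 2 in plasma cell-like cells. With no filter on low counts 6 were called in neutrophil-like cells. Over the alternatives the adjusted p of Cebpb ranged from 1.44e-07 to 1 in neutrophil-like and from 2.59e-05 to 0.962 in natural killer cell-like cells, where it was left out as a possible free RNA gene in 1 setting. That of Lifr in plasmacytoid dendritic cell-like cells ranged from 0.0268 to 1. As a share of named cells, T cell-like cells differed by 0.449, neutrophil-like cells by 0.0230 and B cell-like cells by 4.95 percentage points (1.14 of all cells). The share of cells that are not hepatocyte-like was not run, since no main cluster was. At resolution 0.5 the plasmacytoid dendritic cell-like cluster (556 cells) held cells of the Cdk8-rich libraries alone, so that class could not be fitted there. With at least 30 cells plasma cell-like and plasmacytoid dendritic cell-like cells could not be fitted.

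The replicate block took replicate numbers 1 to 3 as pairs. Correlations of equal numbers were 0.80, -0.39 and -0.81 over 3 pairs, and 0 controls were closest to their own number. These correlations follow the library kind: control 1 had 0.78 to 0.81 with SMF 1 to 4, and control 3 had 0.91 with SMF 5. They therefore cannot tell whether the numbers pair the samples. With the block 5 genes were called in plasmacytoid dendritic cell-like cells. The interferon list did not pass in T cell-like (median 0.28, adjusted p = 0.0705) or natural killer cell-like cells (0.078, adjusted p = 0.361), and plasma cell-like cells had a log2 fold change in cell number of -0.497 (adjusted p = 0.616). For erythroid-like cell numbers edgeR with the block gave an adjusted p of 4.61e-07. SMF 1, 2 and 3, the SMF libraries in that fit, held no cell of that class under the main naming, so no fold is given. Clustering the unnamed cells again named 56, 62 and 12 in them and 9 in control 1. The call thus follows the naming and the library kind, and no difference between the groups is read from it.

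Leaving out 1 library gave 0 to 1 genes in natural killer cell-like and 0 to 210 in plasmacytoid dendritic cell-like cells. The 1, Arf6, and the 210, of which 183 were lower, came without SMF replicate 5. That fit has only Cdk8-rich SMF libraries against mostly Cdk8-poor controls, so it nearly follows the library kind. Lists past the threshold ranged from 5 to 12 in T cell-like (5 without control replicate 2), 4 to 11 in plasma cell-like (4 without control replicate 3) and 5 to 7 in plasmacytoid dendritic cell-like cells (7 without control replicate 1). Without control replicate 3 complex I did not pass in 5 classes, all but neutrophil-like cells, and complexes II to V not in 4; without control replicate 1 and without SMF replicate 5 the interferon list passed in neither T cell-like nor natural killer cell-like cells. The share difference ranged from -4.01 to 4.02 in B cell-like, -3.93 to 1.90 in T cell-like, -4.28 to -1.78 in natural killer cell-like, -1.02 to 0.561 in neutrophil-like, -0.0245 to 0.184 in plasma cell-like and 0.00975 to 0.248 in plasmacytoid dendritic cell-like cells. The extremes below 0 for B cell-like and plasma cell-like cells came without control replicate 3 and without SMF replicate 5; those above 0 for T cell-like and neutrophil-like cells came without SMF replicate 3 and without control replicate 1. The smallest differences for natural killer cell-like and plasmacytoid dendritic cell-like cells came without control replicate 1. Piezo1 ranged in T cell-like cells from -0.064 to 0.18, Mcu from -0.038 to 0.29 and Atp2a2 from -0.15 to 0.29.

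With the library kind as a covariate, 1 gene was called in B cell-like, 1 in neutrophil-like, 1 in plasma cell-like and 28 in plasmacytoid dendritic cell-like cells. The lists past the threshold were 5 in B cell-like, 8 in T cell-like, 5 in natural killer cell-like, 3 in neutrophil-like, 5 in plasma cell-like and 2 in plasmacytoid dendritic cell-like cells, all higher in SMF apart from phagocytosis and efferocytosis in natural killer cell-like (median -0.46) and calcium-dependent signalling in plasma cell-like cells. With an estimated correlation or fry, 0 of them passed in any class (smallest adjusted p = 0.137 and 0.484). List medians whose test turned, some with the sign of the median kept, were, in B cell-like cells, ribosomal 0.10, complex I 0.046, complexes II to V 0.032, Nrf2 0.10, lymphocyte transcripts 0.14, neutrophil maturation -0.13 and neutrophil transcripts -0.20. For T cell-like cells they were ribosomal 0.067, complex I 0.18, complexes II to V 0.087, Nrf2 0.15, neutrophil maturation -0.085, neutrophil transcripts -0.14, hepatocyte transcripts -0.10 and secreted plasma proteins -0.12. In natural killer cell-like cells they were ribosomal 0.076, complex I 0.13, complexes II to V 0.12, lymphocyte transcripts 0.046, neutrophil maturation -0.013 and neutrophil transcripts -0.20. In neutrophil-like cells they were ribosomal 0.56, complex I 0.26, complexes II to V 0.23 and mitochondrial genome 0.062, and Rpl38 had 0.39. In plasma cell-like cells they were ribosomal 0.13, complex I 0.14, complexes II to V 0.14, Nrf2 0.13, antigen presentation 0.17 and lymphocyte transcripts -0.019, and in plasmacytoid dendritic cell-like cells ribosomal 0.13, complex I 0.26 and complexes II to V 0.28. Piezo1 had -0.33 in T cell-like cells, Mcu -0.17 and Atp2a2 -0.25.

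Within the Cdk8-rich libraries, 3 genes were called in B cell-like, 3 in T cell-like, 4 in natural killer cell-like, 4 in neutrophil-like and 3 in plasma cell-like cells and 6 over all cells. Named among them were Dusp2 in B cell-like (adjusted p = 3.00e-04), Arf6 and Cebpb in natural killer cell-like (6.42e-04 and 0.0393) and Cebpb in neutrophil-like cells (3.96e-04), against up to 1 under other settings. Cebpb was also called in neutrophil-like cells by DESeq2 (0.00461), with no filter on low counts (1.44e-07) and with the kind as a covariate (0.0163), and in natural killer cell-like cells by DESeq2 (2.59e-05); Arf6 was also called there without SMF replicate 5 (0.0343). Lists past the threshold were 6 in B cell-like (4 higher), 1 in T cell-like (1 higher), 4 in natural killer cell-like (3 higher), 2 in neutrophil-like (1 higher), 2 in plasma cell-like (0 higher) and 1 in plasmacytoid dendritic cell-like cells (1 higher). The share differed by -4.58 in B cell-like, -1.61 in neutrophil-like and -0.0200 in plasma cell-like cells. The mitochondrial share differed by 0.085 in B cell-like, 0.0283 in T cell-like, 0.0183 in natural killer cell-like, 0.0413 in neutrophil-like, 0.00554 in plasma cell-like and 0.000636 in plasmacytoid dendritic cell-like cells and by 0.0655 over all cells. List medians whose test turned, some with the sign of the median kept, were mitochondrial genome 0.17, neutrophil maturation 0.070 and neutrophil transcripts 0.25 in B cell-like cells. They were mitochondrial genome 0.017, ribosomal 0.024, complex I 0.0079, neutrophil maturation 0.30, neutrophil transcripts 0.92, hepatocyte transcripts 1.38 and secreted plasma proteins 1.38 in T cell-like cells. They were neutrophil maturation 0.40 in natural killer cell-like cells, and mitochondrial genome 0.38, ribosomal 0.71 and complex I 0.14 in neutrophil-like cells. They were mitochondrial genome 0.10, ribosomal 0.013 and complexes II to V 0.068 in plasma cell-like cells, and ribosomal 0.082 and complex I -0.064 in plasmacytoid dendritic cell-like cells. Rpl38 had 0.23 in B cell-like, 0.26 in T cell-like and 1.75 in neutrophil-like cells, and Rpl35 0.065 in T cell-like and 0.072 in natural killer cell-like cells. Ndufs4 had 0.017 in T cell-like cells, Sod1 0.16, Stim1 0.15, Piezo1 -0.061 and Atp2a2 -0.22.

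Within the Cdk8-poor libraries, 27 genes were called in B cell-like, 85 in T cell-like, 8 in natural killer cell-like, 5 in neutrophil-like, 41 in plasma cell-like and 22 in plasmacytoid dendritic cell-like cells and 97 over all cells. Lists past the threshold were 8 in B cell-like (8 higher), 10 in T cell-like (8 higher), 4 in natural killer cell-like (4 higher), 8 in neutrophil-like (6 higher), 7 in plasma cell-like (5 higher) and 9 in plasmacytoid dendritic cell-like cells (8 higher); pooled, 1 of 11 in T cell-like and 1 of 9 in natural killer cell-like cells were higher, and 0 in the other classes. The share differed by -6.77 in natural killer cell-like, 1.05 in neutrophil-like, 0.540 in plasma cell-like and 0.360 in plasmacytoid dendritic cell-like cells. In neutrophil-like cells it was -0.155 with the stricter cell filter and -0.289 at Leiden resolution 0.5. List medians whose test turned, some with the sign of the median kept, were, in B cell-like cells, ribosomal 0.26, complex I 0.21, complexes II to V 0.13, Nrf2 0.23, lymphocyte transcripts 0.25, hepatocyte transcripts 0.32, secreted plasma proteins 0.30 and neutrophil maturation -0.25. For T cell-like cells they were ribosomal 0.13, complex I 0.35, complexes II to V 0.17, Nrf2 0.27, cytotoxicity 0.10, neutrophil maturation -0.10 and neutrophil transcripts -0.17. They were ribosomal 0.18, complex I 0.31, complexes II to V 0.21 and lymphocyte transcripts 0.35 in natural killer cell-like cells, and ribosomal 0.38, complex I 0.34, complexes II to V 0.22 and Nrf2 -0.036 in neutrophil-like cells. They were ribosomal 0.20, complex I 0.13, complexes II to V 0.15, Nrf2 0.18 and antigen presentation 0.21 in plasma cell-like cells, and ribosomal 0.21, complex I 0.25 and complexes II to V 0.23 in plasmacytoid dendritic cell-like cells. Apoa1 had 0.13 in B cell-like cells, and in T cell-like cells Uqcrfs1 had 0.0088, Piezo1 -0.67, Mcu -0.51 and Atp2a2 -0.34.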

Other observations

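The account of immediate early genes, of the kinds within each class and of unnamed cells here was chosen after seeing the data.

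Immediate early and dissociation stress genes, which include Fos, Jun and the heat shock gene Hspa1a, were higher in SMF in all 6 classes once the library kind was a covariate, with medians of 0.55 to 2.34; pooled, the list passed in 0 classes, and with an estimated correlation or fry 0 kind-adjusted lists passed in any class (smallest adjusted p = 0.137 and 0.484). Within the Cdk8-poor libraries its medians were 0.97 to 2.28, and within the Cdk8-rich libraries 0.05 to 1.57. In plasmacytoid dendritic cell-like cells 26 of the 28 genes called with the kind as a covariate were higher in SMF, among them the signalling genes Fos, Rgs1, Zfp36, Ccl4 and Klf6. In this class control 1, the only Cdk8-rich control, held 10 cells, and the only Cdk8-poor SMF library was SMF 5, with 107. The calls may thus rest on single libraries. With the kind as a covariate and the preset correlation alone, endoplasmic reticulum stress genes were higher in 5 classes, inflammatory cytokines and chemokines in B cell-like and T cell-like cells, the cell cycle list in 2 classes and erythrocyte transcripts in 3. By the same test, lost with an estimated correlation, interferon-stimulated genes were higher in B cell-like, T cell-like, natural killer cell-like and plasma cell-like cells.

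Liver-resident cells were found among the unnamed cells, which fell into 25 smaller clusters. Kupffer cell-like cells, with the complement genes C1qa, C1qb and C1qc, numbered 41 in control 2, 92 in control 3 and 242 in SMF 5, the libraries in which they were found. Sinusoidal endothelial-like cells, led by Ptprb and Sparc, numbered 6, 57 and 16 in the controls and 7, 8, 9, 29 and 131 in the SMF libraries. Hepatocyte-like cells, led by Alb and Fabp1, numbered 50, of which 36 were in SMF 4. Monocyte-like cells, with Lyz2 and Ccl2, numbered 12 in control 2, 2 in control 3 and 113 in SMF 5. Migratory dendritic cell-like cells, led by Fscn1, numbered 17, 6 and 75 in these libraries, and basophil-like cells, with Cpa3, 30, 18 and 39. These numbers were too small, or confined to 1 kind of library, for a comparison of the groups.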
